A study of Mus musculus with 6 samples.

How the data were processed

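Samples labelled as bone marrow mesenchymal stromal cells (MSC) of C57BL/6 mice were profiled by RNA sequencing in 6 libraries, 3 with the targeted deletion of Hes1 (Hes1 KO) and 3 wild type (WT). Per the labels' protocols, mice carrying a floxed Hes1 allele were crossed with Prx1Cre mice, in which Cre is made in early limb bud mesenchyme, RNA was extracted with Qiagen RNeasy columns, and libraries were made with a kit that selects polyadenylated RNA and keeps the strand. The labels call the animals Hes1 knockout, and their protocols name heterozygous floxed mice, so the number of deleted alleles is not given in the sources used here. The groups and replicate numbers were taken from the sample titles. The series description also speaks of resistant cell lines and of an NFA treatment, which no sample label carries, and no such comparison was made.

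The deposited table holds whole-number read counts for 26988 genes by symbol, and every gene has a count in at least 1 library. The authors counted reads with featureCounts, per the name of the deposited table, and used the genome build GRCm39, edgeR and limma, per the submitters' processing notes. The aligner, the annotation, the strand setting of the counting and the tool versions are not given in the sources used here. Without the strand setting, reads of a gene and of an antisense partner cannot be told apart, and genes with near-identical copies (Gapdh, haemoglobin, histocompatibility and clustered protocadherin genes) are uncertain. Gene positions on GRCm39 were not used here. Gene spans came from the RefSeq annotation of GRCm38.p6 by symbol, which gave a span for 26094 genes (96.7%), and served only to class genes by length.

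Counts were tested as deposited with edgeR 4.0.16 (R 4.3.3): genes were filtered with filterByExpr, which left 14756, libraries were scaled by TMM, and Hes1 KO was compared with WT by the quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. The quasi-likelihood dispersions were fitted with the legacy option off, and the option that the installed version uses by default was added as an alternative. Standard errors of log2 fold changes are approximate, being the fold change divided by the square root of its F statistic. CPM values and their sums are counts scaled to a library's total without the TMM factors, unlike the fold changes. In TMM scaling WT replicate 1 had a factor of 1.60 and WT replicate 3 of 0.397, and the other 4 libraries had factors of 0.975 to 1.21. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with camera with an estimated correlation and with fry. Before the data were examined, 32 gene lists were fixed. The list of sex chromosome genes was left out of these tests, and the 27 other lists with at least 5 tested members entered them. A group with 0 counts in all its libraries gives a lower bound of the fold, computed from 3 counts over that group.

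The alternatives fixed before the data were examined were other scalings, other filters, DESeq2 1.42.0, limma-voom, quality weights, robust fits, stricter thresholds, the replicate number as a block, and leaving out each library in turn. Leaving out WT replicate 1 gave a fit of 3 Hes1 KO and 2 WT libraries with 16190 genes, called the 5-library fit below. Hes1 and Nfatc2 are named always. The rule for other names, set before the data were examined, took the 12 largest increases and 12 largest decreases among genes that passed, had a mean of at least 1 CPM in the higher group, kept the groups apart in every library and were not predicted models. As no gene passed with 6 libraries, the rule took the 10 smallest p. It also took up to 4 passing members of each described list, or the 2 smallest p, and the 2 most abundant members of marker lists. Applying the same rule to the 5-library fit was decided after the data were seen.

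The scripts were tested on simulated data made from these libraries, and recovery depended on the spread between libraries. With the dispersions estimated from these data and 6 libraries, 13 of 100 simulated 4-fold and 81 of 100 simulated 16-fold changes were recovered, with 3 false calls among 97. In the 5-library fit, 29 of 100 and 97 of 100 were recovered, with 8 false calls among 134. At a dispersion of 0.05 for every gene, 100 of 100 and 100 of 100 were recovered with 6 libraries (8 false calls among 208), and 99 of 100 and 100 of 100 in the 5-library fit (12 among 211). Camera with the preset correlation was tried on simulated data of the 5-library layout, with the same dispersion for every gene. It called a simulated list shift and 0 of 20 lists with no shift. Camera was not tried on simulated data of all 6 libraries, nor with the dispersions estimated from these data. Genes were drawn independently of each other there. The 6 lists that camera called in these data had estimated correlations of 0.0547 to 0.448, so false calls among correlated genes were not tested. Intervals of single-library values are Wilson 95% intervals, and these and the floors of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. Figures were drawn with matplotlib 3.10.9, and the library checks used scipy 1.17.1.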

Results

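RNA sequencing compared libraries labelled as bone marrow MSC, the stromal cells that support bone and blood formation, with and without the deletion of Hes1, a transcriptional repressor downstream of Notch. The 3 Hes1 KO libraries held 22131465, 21170047 and 20563116 counts. The WT libraries were shallower, with 66167 counts in WT replicate 1, 5812598 in WT replicate 2 and 12109170 in WT replicate 3. WT replicate 1 had a count for 7590 genes, against 20592 to 22607 in the other libraries, and its single count was worth 15.1 CPM. In WT replicate 3 the 10 most abundant genes took 50.03% of all counts, against 5.97% to 16.4% in the others. The labels do not say whether libraries of a group came from separate animals or cultures, so the p-values measure the spread between these libraries. Each group held libraries with abundant Xist and libraries with Y transcripts (values below), so neither group was a single animal sequenced repeatedly.

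The targeted gene was examined first. Hes1 was counted 185, 220 and 255 times in the Hes1 KO libraries, or 8.36, 10.4 and 12.4 CPM (mean 10.4 ± 2.02 SD, n = 3). WT replicate 2 had 310 counts of Hes1 (53.3 CPM, Wilson 95% interval 47.7 to 59.6) and WT replicate 3 had 345 (28.5 CPM, 25.6 to 31.7). WT replicate 1 had 0 counts (Wilson 95% upper limit 58.1 CPM), so that library does not check its label. In the 5-library fit Hes1 fell by 2.55 on the log2 scale (SE 0.31, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0294), and 489 genes that passed fell by at least as much. With all 6 libraries the log2 fold change of Hes1 was -2.12 (SE 1.01) and did not pass (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.364). Counts were summed over the whole gene, so the table does not separate the deleted part from the rest. The libraries also held few stromal transcripts and differed in their shares of blood cell transcripts (values below). A fall of Hes1 through its deletion was therefore not told apart from one through a different mix of cells.

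Nfatc2, a calcineurin-regulated transcription factor named in the series title, was at 24.1, 17.1 and 15.8 CPM in the Hes1 KO libraries and at 15.1, 10.7 and 3.22 CPM in WT replicates 1, 2 and 3. The value of WT replicate 1 rests on 1 count (Wilson 95% interval 2.67 to 85.6 CPM). The log2 fold change of Nfatc2 was 0.99 (SE 0.43) with all libraries and 1.09 (SE 0.27) in the 5-library fit, and neither passed (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.33 and 0.0519). Among 12 tested genes of the NFAT and calcineurin list, 7 had higher and 5 lower levels in Hes1 KO. That list was not shifted (camera with Benjamini-Hochberg adjustment, adjusted p = 0.718). Its members Rcan1 and Rcan3, calcineurin regulators, rose by 1.66 and 1.44 (log2) in the 5-library fit, where Nfat5 fell by 1.41 and Ppp3cc, a calcineurin subunit, also fell (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0329, 0.0303, 0.0317 and 0.0372).

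**Figure D1:**
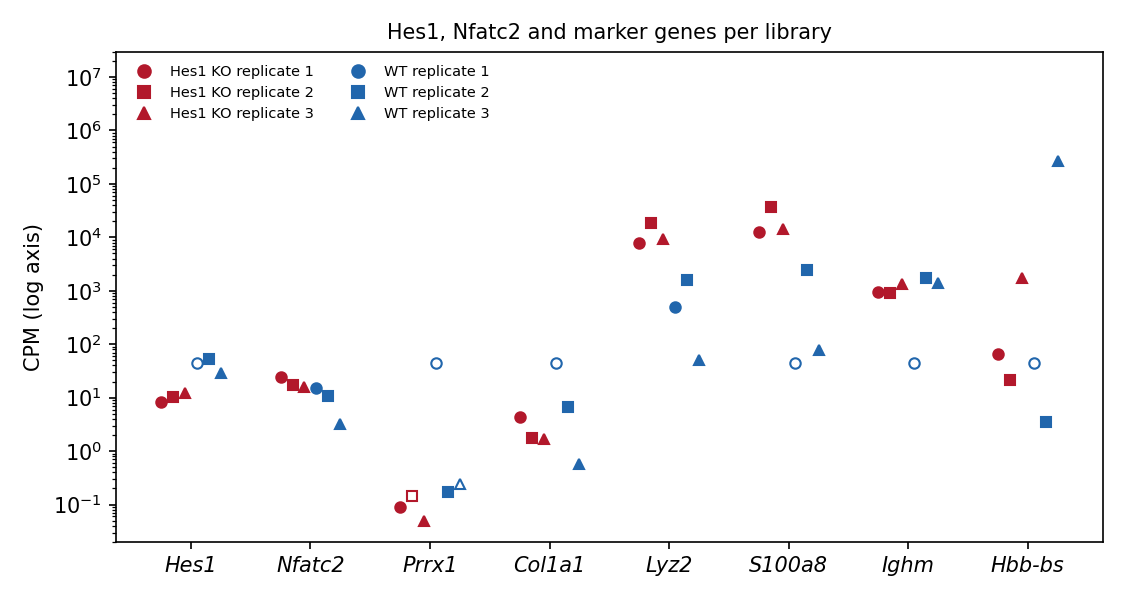
CPM (log axis) of Hes1, Nfatc2, the stromal genes Prrx1 and Col1a1 and the blood cell genes Lyz2, S100a8, Ighm and Hbb-bs in each of the 6 libraries. Filled points are measured values and open points are genes with 0 counts, drawn at the level of 3 counts (45.3 CPM in WT replicate 1); Hes1 lies at 8.36 to 12.4 CPM in Hes1 KO and at 28.5 and 53.3 CPM in WT replicates 3 and 2.

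The libraries of both groups held abundant transcripts of blood cells and few of stromal cells. Prrx1, the mesenchymal gene whose promoter drives the Cre line, had 2, 0 and 1 counts in Hes1 KO and 0, 1 and 0 in WT. Col1a1, the main bone and fibroblast collagen gene, had 96, 38 and 35 counts in Hes1 KO and 0, 39 and 7 in WT. The neutrophil markers summed to 4.97%, 13.1% and 6.01% of counts in Hes1 KO and to 1.16%, 1.55% and 0.0367% in WT. The macrophage markers summed to 1.55%, 2.82% and 1.66% in Hes1 KO and to 0.963%, 0.443% and 0.0926% in WT. The widest Wilson 95% intervals of these shares were those of WT replicate 1, 1.08% to 1.25% for neutrophil and 0.891% to 1.04% for macrophage markers. Erythroid and megakaryocyte markers took 42.5% of WT replicate 3 (Wilson 95% interval 42.5% to 42.6%), where the beta-globin gene Hbb-bs alone had 3189021 counts, and at most 0.324% of any other library.

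**Figure D2:**
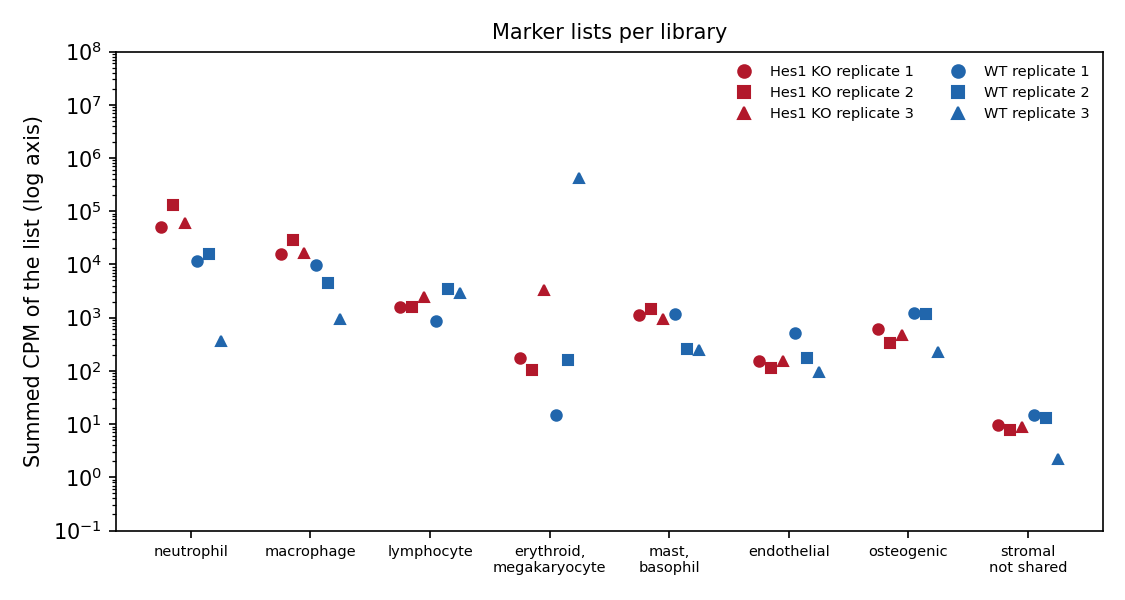
Summed CPM (log axis) of marker lists in each of the 6 libraries, with 1 point per library. The list named stromal not shared holds 8 stromal genes taken here as not made by blood cells, which was not tested. The neutrophil sums of the Hes1 KO libraries lie above those of the WT libraries, the erythroid and megakaryocyte sum of WT replicate 3 stands apart at 42.5% of its counts, and the value of WT replicate 1 for the stromal list rests on 1 count.

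With all 6 libraries no single gene passed, and 9 of the 10 genes with the smallest p were higher in Hes1 KO. Fcgr1, the high-affinity receptor for IgG of monocytes and macrophages, had 558, 331 and 291 counts in Hes1 KO and 0, 2 and 1 in WT (log2 fold change 6.03, SE 0.71). S100a4, a calcium-binding protein, followed with 4.22 (SE 0.59), and the cytokine gene Tnfsf13 with 4.59 (SE 0.66). Cd63, Sqor, Vill, Ifi207, Glipr2 and Ms4a6b had log2 fold changes of 2.48 to 3.38, and the predicted gene Gm51891 had one of -5.06 (SE 0.83). None of these 10 passed (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.31 for each). edgeR called 0 of 14756 genes and gave 2200 with an unadjusted p under 0.05, while limma-voom called 0 and DESeq2 called 832, of which 214 rose and 618 fell. In the DESeq2 fit the median log2 fold change of all genes was -1.09, against 0.03 in edgeR, and 563 of its 832 calls were also made in the 5-library fit. The 3 Hes1 KO libraries lay on one side of the 3 WT libraries for 3791 genes (25.7%). The 10% that chance gives is an average over splits of the libraries, and a single split can exceed it since genes vary together. This share was not computed for other splits.

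Leaving out WT replicate 1 changed the outcome: 2513 of 16190 genes passed in the 5-library fit, of which 1204 rose and 1309 fell in Hes1 KO. Fcgr1 rose by 6.07 (log2, SE 0.43), the interferon-inducible gene Ifi204 by 4.85 (SE 0.62), the macrophage lectin Siglec1 by 5.14 (SE 1.35), Wfdc17 by 5.22 (SE 0.79) and Ms4a8a by 5.28 (SE 0.54). For Ms4a8a the value with all libraries was 2.74, as its 2 counts in WT replicate 1 make 30.2 CPM, above the 7.23 to 13.7 CPM of the Hes1 KO libraries. Batf3, Map6, Pdzd3, Stab1, Tcea3, Rnase2b and Ptgs2os2 also rose, from 0 counts in WT replicates 2 and 3. Their mean CPM in Hes1 KO was at least 6.10-fold (Pdzd3) to at least 13.1-fold (Tcea3) higher than a floor of 3 counts over both WT libraries. The peptide transporter Slc15a2 fell by 8.83 (SE 1.22), the phosphatase Dusp8 by 5.96 (SE 1.20), the meiotic gene Rec114 by 5.74 (SE 1.00) and the protease Ctse by 4.88 (SE 1.07). Igfn1, Pard3bos1, Crybb3, Pcdhga11, Fjx1, Pcdhga9, Bach2os and Ttc39a fell by 4.43 to 5.54. Bach2os, Pard3bos1 and Ptgs2os2 are antisense genes and Pcdhga9 and Pcdhga11 share exons with their cluster, so their values are uncertain. The largest adjusted p among the genes named here was 0.0484, for Rnase2b (edgeR with Benjamini-Hochberg adjustment). The 2513 calls carry an imbalance of the sex chromosome genes, for which no term was fitted. Ddx3y of the Y chromosome was at 205 and 42.2 CPM in WT replicates 2 and 3, at 61.9 CPM in Hes1 KO replicate 2 and at 1.27 and 0.146 CPM in Hes1 KO replicates 1 and 3. Xist, transcribed from the inactive X chromosome, was at 3.10 and 71.9 CPM in those WT libraries and at 1221, 11 and 1004 CPM in Hes1 KO replicates 1, 2 and 3. Both WT libraries of that fit thus had Y transcripts, while 2 of its 3 Hes1 KO libraries had little of them and abundant Xist.

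The genes that rose and fell in the 5-library fit were of different kinds. Predicted gene models made up 6.64% of those that rose and 36.1% of those that fell, against 19.0% of those tested. Among protein-coding genes, a span over 100 kb (GRCm38.p6) was found for 4.56% of those that rose and 30.0% of those that fell, against 12.1% of those tested. WT replicate 2 also stood apart in these classes, with 17.1% of its protein-coding counts in such long genes and 7.79% of its counts in predicted models, against 6.46% to 10.8% and 2.26% to 4.08% in the other libraries. Among noncoding RNA, chosen after their values were seen, Malat1 was at 13895, Rn7sk at 3017 and Rpph1 at 1962 CPM in WT replicate 2, and at no more than 3340, 212 and 85.2 CPM in any other library.

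Gene groups were then compared with the rest of the genes. By camera with all 6 libraries, neutrophil and macrophage markers, oxidative phosphorylation, cell cycle and glycolysis and hypoxia genes were shifted up in Hes1 KO and Wnt pathway genes were shifted down. No list kept its call with an estimated correlation (adjusted p = 0.556 with an estimated correlation for each of the 6 lists, camera with Benjamini-Hochberg adjustment). With the preset correlation, the Wnt call was lost without WT replicate 2 (median -1.18) and without WT replicate 3 (median -1.13). It was also lost with no filter on low counts (median -0.27, with 11 of 25 genes higher), with library size alone (-0.82), with the replicate block (-0.90) and with WT replicate 2 alone against Hes1 KO (-1.43). The glycolysis and hypoxia call was lost without WT replicate 3 (median 0.52) and with WT replicate 2 alone (0.56). The rotation test fry asks another question, whether the genes of a list move on balance one way, and sets them against no change and not against other genes. With all 6 libraries fry called 0 lists (smallest Benjamini-Hochberg adjusted p = 0.0578). In the 5-library fit it called complement genes, ATF4 and unfolded protein response genes and macrophage markers higher in Hes1 KO (fry, Benjamini-Hochberg adjusted p = 0.00442, 0.0412 and 0.0462), and Wnt and Notch genes lower (adjusted p = 0.0075 and 0.0291).

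All 15 neutrophil markers had higher levels in Hes1 KO, with a median log2 fold change of 3.19 (camera, Benjamini-Hochberg adjusted p = 3.07e-06, and adjusted p = 0.556 with an estimated correlation). Of them, 0 passed over all genes and 4 passed when adjusted over the list alone. S100a8 and S100a9, the calprotectin subunits, had means of 21304 ± 14073 and 24413 ± 15430 CPM (SD, n = 3) in Hes1 KO. In WT replicates 1, 2 and 3, S100a8 was at 0, 2482 and 76.5 CPM and S100a9 at 0, 2320 and 88.4 CPM. The chemokine receptor Cxcr2 was the 1 marker of the 15 that rose in the 5-library fit, by 3.15 (SE 0.59, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.033). All 18 tested macrophage markers had higher levels, with a median of 1.75 (camera, Benjamini-Hochberg adjusted p = 2.75e-07, and adjusted p = 0.556 with an estimated correlation). Of these, 0 passed over all genes and 7 adjusted over the list alone. Of 20 macrophage markers 10 rose in the 5-library fit, among them Fcgr1, Aif1 by 3.06, Cd68 by 2.46 and Mpeg1 by 2.29. With all libraries Cd68 was at 0.67 and Mpeg1 at 0.68, as WT replicate 1 had 18 and 188 counts of them, or 272 and 2841 CPM, above every Hes1 KO library (103 to 126 and 1151 to 1592 CPM). Lyz2, the lysozyme of myeloid cells, was the most abundant at 7970, 18329 and 9426 CPM in Hes1 KO and 499, 1597 and 51.4 CPM in WT. Of the 32 oxidative phosphorylation genes 30 had higher levels (median 1.22, camera, Benjamini-Hochberg adjusted p = 2.46e-06, and adjusted p = 0.556 with an estimated correlation). Of these, 9 rose in the 5-library fit, including Ndufv2 by 1.55 and Ndufa9 by 1.20 of the respiratory chain's NADH dehydrogenase, and Cox5a by 0.98 of cytochrome oxidase. Ndufa9 was at 0.08 with all libraries, with 302 CPM from 20 counts in WT replicate 1 and 87.5 to 117 CPM in Hes1 KO.

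Of 36 cell cycle genes 33 had higher levels in Hes1 KO (median 0.94, camera, Benjamini-Hochberg adjusted p = 8.42e-05, and adjusted p = 0.556 with an estimated correlation). Ccnb2 rose by 1.09, Birc5 by 1.36 and Mcm5 by 1.19 in the 5-library fit, the 3 members that passed there. Summed CPM of the cell cycle list overlapped between the groups, at 8953, 4795 and 8590 in Hes1 KO and 6287, 7570 and 1648 in WT replicates 1, 2 and 3. Of 24 glycolysis and hypoxia genes 19 had higher levels (median 0.55, camera, Benjamini-Hochberg adjusted p = 0.00995, and adjusted p = 0.556 with an estimated correlation). Their summed CPM were 2486 to 2999 in Hes1 KO, and 3053, 1544 and 335 in WT replicates 1, 2 and 3. With TMM factors of 1.60 for WT replicate 1 and 0.975 to 1.17 for Hes1 KO, WT replicate 1 lies below every Hes1 KO library. Without WT replicate 1, 6 of 25 rose and 1 fell. Ldha, lactate dehydrogenase, rose by 1.75, Pgk1 by 1.86 and the lactate exporter Slc16a3 by 2.60, while Adm, a hypoxia-induced peptide hormone, fell by 3.04. Of 10 Wnt pathway genes 7 had lower levels (median -1.24, camera, Benjamini-Hochberg adjusted p = 0.0154, and adjusted p = 0.556 with an estimated correlation). Without WT replicate 1, 7 of 11 fell, among them Lef1, a Wnt-responsive transcription factor also made by early lymphocytes, by 2.51, the stem cell receptor Lgr5 by 1.85 and the pathway inhibitor Nkd2 by 2.12. The Wnt genes summed to 372 CPM in WT replicate 2, the library that stood apart in long genes, and to 149 CPM in WT replicate 3. They summed to 89.3, 66.8 and 117 CPM in Hes1 KO, while the 2 counts in WT replicate 1 make 30.2 CPM, below every Hes1 KO library. With all 6 libraries the fold changes also use the TMM factors, 1.21 for WT replicate 2 and 0.397 for WT replicate 3. These put WT replicate 3 above WT replicate 2. The 5-library fit has its own factors, which are not given here. Beside these groups stands the higher share of neutrophil and macrophage transcripts in the Hes1 KO libraries and the erythroid share of WT replicate 3.

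The Notch list, which includes Hes1 itself, was not shifted by camera with all libraries, with 13 of 22 members lower (median -0.37, camera, Benjamini-Hochberg adjusted p = 0.118). Camera called it without WT replicate 1 when libraries were thinned to WT replicate 2 (median -0.82), but not in the 5-library fit (Benjamini-Hochberg adjusted p = 0.068, and adjusted p = 0.629 with an estimated correlation). Notch genes summed to 836 to 898 CPM in Hes1 KO and to 1406, 1512 and 341 CPM in WT replicates 1, 2 and 3. Members that fell in the 5-library fit were 5 of 23: Hes1, the related repressor Hes5 by 2.04, the Notch regulator Dtx1 by 2.89, the coactivator Maml2 by 3.41 and Id3, an inhibitor of DNA binding, by 2.03. Inflammatory and NF-kB genes were not shifted either, with 18 of 28 higher (median 0.18, camera, Benjamini-Hochberg adjusted p = 0.248). The neutrophil chemokine Cxcl2 rose by 3.56 in the 5-library fit, while the NF-kB subunits Relb and Nfkb2 fell by 2.55 and 1.19 and the NF-kB inhibitors Nfkbie and Tnfaip3 fell by 2.07 and 1.97. WT replicate 2, with the highest Notch sum, was also the library that stood apart in long genes. Whether that or a different mix of cells accounts for the falls of these Notch and NF-kB genes was not tested. The interleukin gene Il6 had 184, 247 and 120 counts in Hes1 KO and 0, 40 and 65 in WT (log2 fold change 0.03, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.991), and it was chosen after its values were seen. Interferon genes had a median of -0.19 while camera gave the opposite direction (Benjamini-Hochberg adjusted p = 0.815), and camera called them without WT replicate 2 (median -0.49) and without WT replicate 3 (median 1.34). They summed to 8430 CPM in WT replicate 3, of which Rsad2 alone made 6361 CPM, and to 1096 to 2343 CPM in the other libraries.

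**Figure D3:**
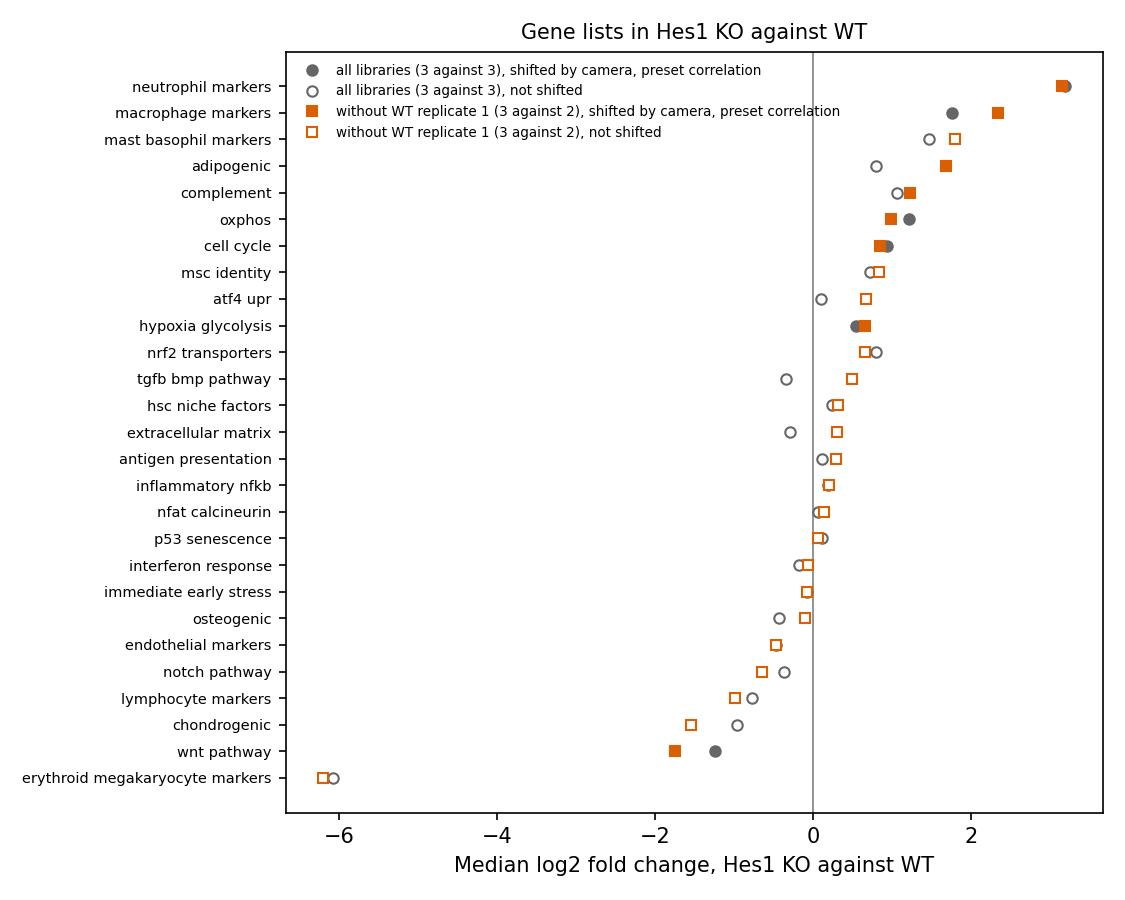
Median log2 fold change of Hes1 KO against WT (horizontal axis) for the 27 tested gene lists, with all 6 libraries (grey circles) and without WT replicate 1 (orange squares). Filled points were shifted by camera with a preset correlation and open points were not; neutrophil markers lie highest at 3.19 and 3.15, and no filled point with all 6 libraries kept its call with an estimated correlation (adjusted p = 0.556), nor did any of the 8 without WT replicate 1 (adjusted p = 0.629 to 0.789).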

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

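Settings with WT replicate 2 alone, with thinned libraries, without erythroid genes and with legacy dispersions were chosen after seeing the data. The count of 0 changed genes became 832 with DESeq2, 2513 without WT replicate 1, 6210 with WT replicate 2 alone against Hes1 KO (its spread taken from the Hes1 KO libraries) and 1826 without WT replicate 1 and thinned to WT replicate 2, of which 1624 were among the 2513; it stayed at 0 in the other edgeR and limma settings run. With single libraries left out it was 0 to 2513, and 0 for each library but WT replicate 1. As no gene passed, a share of changed genes that rose has no value. Hes1 was at -2.34 with DESeq2, -2.11 with WT replicate 2 alone and -2.64 when thinned, all past the threshold, and at -2.55 to -1.62 with single libraries left out (edgeR, limma or DESeq2 with Benjamini-Hochberg adjustment, adjusted p = 0.00517 to 0.795 over all settings). Nfatc2 passed in no setting run and was at 0.85 to 1.13 with single libraries left out. The 6 shifted lists became 0 with an estimated correlation, 0 with fry (which sets a list against no change, not against other genes) and 10 when thinned, and 6 to 8 with single libraries left out. Klf4, at -0.36 with all libraries, turned to 1.20 without WT replicate 1, 1.27 with WT replicate 2 alone and 1.10 when thinned (-0.83 to 1.20 with single libraries left out); Nkg7, at -1.92, turned to 1.16 without WT replicate 1 and with WT replicate 2 alone (-2.51 to 1.16). The cause was not tested beyond the libraries left out. Over all named genes other than Hes1 and Nfatc2, Klf4 and Nkg7 included, 2317 values were on the same side, 282 newly passed with the same sign and 55 changed sign without passing. Library size alone moved the median of the tested genes to 0.26 and upper-quartile factors to -0.21, from 0.03. DESeq2, run on 26740 genes with no filter on low counts, gave -1.09. Whether the replicate numbers pair the libraries stays open. Same-numbered libraries had correlations of 0.15, 0.01 and 0.24, and differently numbered ones of -0.20 to 0.03. Hes1 KO replicate 2 correlated best with WT replicate 1, at 0.02. With the replicate block 0 genes passed (900 at an unadjusted p under 0.05), Hes1 was at -1.58, Nfatc2 at 0.93 and 9 lists were shifted.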

Other observations

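Marrow stroma and skeletal lineages gave few differences that passed. Osteogenic genes were not shifted, with 8 of 11 lower in Hes1 KO (median -0.44, and 0.35 without WT replicate 2; camera with Benjamini-Hochberg adjustment, adjusted p = 0.495), nor were the stromal identity genes, with 9 of 12 higher (median 0.72, adjusted p = 0.248 by the same test). In the 5-library fit Itgb1, an integrin subunit that blood cells also make, rose by 1.08, and Ebf1, a transcription factor of B cells and of marrow stroma, fell by 3.51 with 3130 CPM in WT replicate 2 and 683 CPM in WT replicate 3 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0473 and 0.0294). The niche factor list had a median of 0.24 and a mean of -0.06, the matrix list a median of -0.29 and a mean of 0.07, the TGF-beta and BMP list a median of -0.34 and a mean of 0.20, and the NRF2 and transporter list a median of 0.79 and a mean of -0.14, so their median and mean differ in sign. The matrix median turned to 0.30 without WT replicate 1 and to 1.10 without WT replicate 2, where 14 of 20 genes were higher in Hes1 KO. Summed over the matrix list, CPM had a mean of 2499 in Hes1 KO and were 1602, 588 and 86.7 in WT replicates 1, 2 and 3. The Hes1 KO mean was 7.41-fold that of WT replicates 2 and 3 (337 CPM), without TMM scaling. Erythroid and megakaryocyte markers took 42.5% of WT replicate 3. The stromal members Col1a1, Col1a2, Col3a1 and Dcn made little of the sum, with means of 2.61, 2.36, 0.53 and 0.19 CPM in Hes1 KO. The fold thus rests on other members and does not show a rise of stromal matrix. Without WT replicate 1 the TGF-beta and BMP median turned to 0.48, with 11 of 19 genes higher, yet the 7 genes that passed all fell, among them Smad7 by 1.99 and Tgfbr3 by 1.48. In the same fit the haem oxygenase Hmox1 of the NRF2 list rose by 3.57.

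Without WT replicate 1, camera also shifted complement genes (median 1.23, camera with Benjamini-Hochberg adjustment, adjusted p = 0.0235) and adipogenic genes (median 1.68, adjusted p = 0.0235) up in Hes1 KO. With an estimated correlation the adjusted p = 0.629 for complement and the adjusted p = 0.688 for adipogenic genes. Properdin, Cfp, rose by 3.02 and Cebpa, a transcription factor of both adipocytes and granulocytes, by 2.11 in that fit, against 0.67 and 0.28 with all libraries. In WT replicate 1 their 38 and 29 counts make 574 and 438 CPM, above every Hes1 KO library (190 to 285 and 133 to 149 CPM). Lymphocyte markers went both ways, with 5 of 15 higher (median -0.77, camera with Benjamini-Hochberg adjustment, adjusted p = 0.815). Ighm, the immunoglobulin heavy chain, was at 930, 912 and 1352 CPM in Hes1 KO and at 1738 and 1392 CPM in WT replicates 2 and 3. In WT replicate 1 Xist was at 2055 CPM and Ddx3y at 0 counts. The labels give no sex.

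Of the tests below, those on genes listed at 0, on marker levels, on the medians without a library and on gene counts across splits were chosen after the result was seen; the spread of ribosomal protein genes and the list counts across splits were set before. WT replicate 1 stands apart from the other libraries. Of 197 genes expected at 10 or more counts at their lowest share in the other libraries, 19 were listed at 0 in it, among them Actb, Ubb and Rpl13a, where Poisson sampling gives 0.00148, which argues against shallow sequencing of WT replicate 1 alone. Among 13 ribosomal protein genes expected at 5 or more counts, 4 were listed at 0 where sampling gives 0.0149, which argues against a different mix of blood cells in WT replicate 1 alone; an earlier limit of 5 such genes was replaced by the sampling expectation after the value was seen. At matched totals of 66167 counts the SD of log2 ratios of 38 ribosomal protein genes against the Hes1 KO profile was 2.77 in WT replicate 1. It was 2.32 times the larger value of WT replicates 2 and 3, which few RNA molecules entering WT replicate 1 would give. Genes listed at 0 widen this spread whatever their cause, so the test cannot single out that source. At these totals WT replicate 1 had a count for 7590 genes, against 6551 in WT replicate 3 and 9163 to 9917 in the other libraries. The labels state the same RNA input for each library. No other biological explanation was tested.

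Stromal markers were near the floor and blood cell genes were abundant in every library. A candidate explanation is RNA mainly from blood cells. Of 22 macrophage markers, 77.3% reached a mean of 10 CPM over the libraries other than WT replicate 1. Of 8 stromal markers taken here as not shared with blood cells, 0% did. The most abundant macrophage marker was Lyz2, at 18329 CPM in Hes1 KO replicate 2, and the labels name no sort or gate that would remove such cells. Loss of stromal identity through Hes1 deletion is argued against by WT replicates 2 and 3, where the stromal markers summed to 13.1 and 2.23 CPM. Which cells held the Hes1 counts stays open.

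Neutrophil and monocyte markers were higher in the Hes1 KO libraries. Haemoglobin transcripts taking the counts of WT replicate 3 could lower its neutrophil share. The neutrophil median was 2.89 (log2) without that library, but TMM scaling already offsets such a loss, so this median is a weak check. Without scaling, neutrophil markers took 1.16% and 1.55% of counts in WT replicates 1 and 2, and 4.97% to 13.1% in Hes1 KO. These shares argue against haemoglobin transcripts as the whole cause. More granulocytes and monocytes among the cells of the Hes1 KO libraries may account for it: without WT replicate 1 the lymphocyte median lay at -4.14 (log2) from the neutrophil median. The lymphocyte median itself changed sign with the libraries, from -0.99 without WT replicate 1 to 0.74 without WT replicate 3. An effect of Hes1 deletion on marrow composition and a difference in how the cells were isolated stay open, no batch is given in the labels, and the series description names an NFA treatment that no sample label carries.

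The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. Each of the 10 splits gave 0 changed genes in edgeR, the real split with 2200 genes at an unadjusted p under 0.05 and the highest other with 1111. For lists shifted by camera with a preset correlation, 7 of the 10 splits gave at least as many as the real value of 6, and the highest other gave 10.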
